A study of Mus musculus with 20 samples.

How the data were processed

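Total RNA of kidney tumours grown in mice from the MSRT1 cell line was sequenced in bulk, with 1 library per mouse. The labels give MSRT1 as renal medullary carcinoma, a kidney cancer that typically lacks the chromatin remodelling subunit SMARCB1. The 20 mice fall into 4 groups of 5, which cross vehicle or GYY4137, a slow-releasing hydrogen sulfide donor, with control antibody (IgG) or an antibody against the checkpoint receptor PD1. The groups are called Veh_IgG, GYY_IgG, Veh_PD1 and GYY_PD1, and GYY_PD1 is called the combination. The labels describe lysis in QIAzol, 1.0 ug of total RNA per library and Nextera XT libraries made from cDNA.

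The deposited table holds 34234 genes in 20 columns. Its values are log2 TPM with no constant added, where TPM is the share of each gene among all transcripts, scaled to a constant total per library. Raised back, each deposited library sums to between 999797 and 1000219 TPM, and a value of 0 TPM is written as a floor of -8.88 log2. The processing notes of the authors name cutadapt, fastp, Salmon 0.14.1, HTSeq 0.11.0 and the mouse build mm10, and do not say which of them made the TPM values or whether genes were filtered. TPM do not keep the number of reads, so the depth of each library is unknown and no counting interval is given. Gene positions and types come from GENCODE M21 on the same build, in which 33908 of the gene names were found.

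Most choices were fixed before the data were examined: the 8 comparisons, the 39 gene lists, the rule for named genes and most of the other settings tried. Genes with at least 1 TPM in at least 5 libraries were tested, 15422 in all. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, as 1 model of the 4 groups over all 20 libraries (16 residual degrees of freedom), with trended variance shrinkage and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Of the comparisons, 5 set 1 group against another, a pair of averages gives each treatment over both levels of the other, and the interaction tests whether the effect of 1 treatment differs with the other. Counts of genes are given on this deposited scale, as designed.

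The median of all tested genes differed between groups by more than 0.1 log2 on the deposited scale. The values of genes and gene lists are therefore given relative to the library median, that is, after the median of the 15422 tested genes was subtracted in each library, a scaling chosen beforehand as an alternative. A difference relative to the library median says how a gene moved against the bulk of the other genes, not whether its amount per cell changed. A further scale, chosen after seeing the data, rescaled TPM to nuclear protein-coding genes, without satellite-like models and without olfactory and vomeronasal receptor genes, and took log2 of the value plus 1. On that scale 11697 genes reached 5 rescaled TPM in at least 5 libraries.

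The 39 lists hold 461 genes, in 22 pathway lists and 17 lists of cell type markers. Lists with at least 3 tested members, 34 of them, were tested with fry in the same model, two-sided, adjusted over the lists of each comparison. fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. Also chosen beforehand were camera with a preset correlation between genes of 0.01, camera with an estimated correlation, and a two-sided permutation test of the mean log2 value of each list per library. The permutation test was exact for 5 libraries against 5, where 252 splits allow no p under 0.00794, and used 100000 resamples for the averages. The other lists had too few members above the filter.

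Named genes were chosen by rule. From the genes past the threshold on the deposited scale, the rule takes the 10 largest rises and the 10 largest falls of each comparison, leaving out provisional names, pseudogenes and variable immunoglobulin and T cell receptor segments. From each list named in the text it takes up to 4 members with the smallest p relative to the library median, of which the text gives some. Pdcd1, Cd274, Smarcb1, Cbs, Cth and Mpst are always given. A gene named outside the rule is marked as chosen after its values were seen.

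A scan of all transcripts for repeats of 225 to 240 bases with at least 50% identity to themselves, in transcripts of at least 400 bases, found 13 gene models that look like major satellite, the tandem repeat of mouse pericentromeric DNA. Their summed share of TPM is called the satellite-like share. The scan and every test that uses it were chosen after seeing the data, as was a boundary of 20% that divides the libraries into 10 under it and 10 over it. The mean TPM of 1042 olfactory and vomeronasal receptor genes, which tumours are not thought to express, served as a measure of background.

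The alternatives were other filters, pseudocounts and scalings, other fits, other thresholds, each library left out in turn, the 2 mice numbered apart from the other 18 left out (GYY_PD1 replicate 1, numbered 1343, and GYY_IgG replicate 5, numbered 4574, where the others run from 2104 to 2135), and, chosen after seeing the data, the combination libraries 1 and 4 left out. The replicate numbers were not taken to pair the mice. Over 30 pairs of libraries with the same number, the median correlation of their deviations from the group means was 0.0149. Over 120 pairs with different numbers it was -0.0091, and 7 of 20 libraries correlated best with their own number. No library was left out of the main results. The analysis was tested on simulated data with the spread of the combination comparison. With the library medians kept and then subtracted, 33 of 100 genes changed 2-fold and 76 of 100 changed 8-fold were called, with 7 unchanged genes. With the medians left in, 9975 unchanged genes were called. A list raised 2-fold was called in 10 of 10 simulations, which together also gave 4 calls of other lists, and no list was called in 10 simulations without a raised list. In the data, the interferon gamma list was about 2-fold higher with GYY4137 alone and did not pass fry. The simulations therefore do not show how often fry finds such a change in these data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.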

Results

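RNA was measured in 20 kidney tumours of the MSRT1 model, 5 mice in each of the groups Veh_IgG, GYY_IgG, Veh_PD1 and GYY_PD1. Values are TPM on a log2 scale, and the depth of the libraries is unknown. The tumours had at least 1 TPM for 14434 ± 291 genes in Veh_IgG, 13817 ± 1240 in GYY_IgG, 13250 ± 1422 in Veh_PD1 and 11106 ± 3431 in GYY_PD1 (mean and SD, n = 5).

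A few gene models held most of the TPM on average. These are shares of TPM and not of reads, whose number is unknown. Gm23935, annotated as a microRNA gene on chromosome 16 (11144125 to 11144181, mm10), took 30.2% of all TPM on average. The 13 satellite-like models, led by Gm10800 on chromosome 2 (98666547 to 98667301), took 7.09% ± 4.17 in Veh_IgG, 25.2% ± 22.6 in GYY_IgG, 32.4% ± 24.4 in Veh_PD1 and 51.8% ± 21.2 in GYY_PD1 (SD, n = 5). The share was higher in the combination than in Veh_IgG in every library (exact permutation p = 0.00794, adjusted over 5 comparisons p = 0.0397), and the other 4 comparisons between groups did not pass (exact permutation p from 0.0952 to 0.198). All 5 combination libraries and no Veh_IgG library lay above 20%, with 2 libraries of GYY_IgG and 3 of Veh_PD1. Nuclear protein-coding genes held 33.9% ± 6.16 of TPM in Veh_IgG and 13.3% ± 8.67 in GYY_PD1 (SD, n = 5). Combination libraries 1 and 4 stood apart: replicate 4 held 83.4% satellite-like TPM and 6659 genes at 1 TPM or more, and replicate 1 had a median Spearman correlation of 0.426 with the other libraries, where the 18 libraries other than these 2 had at least 0.769.

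**Figure D1:**
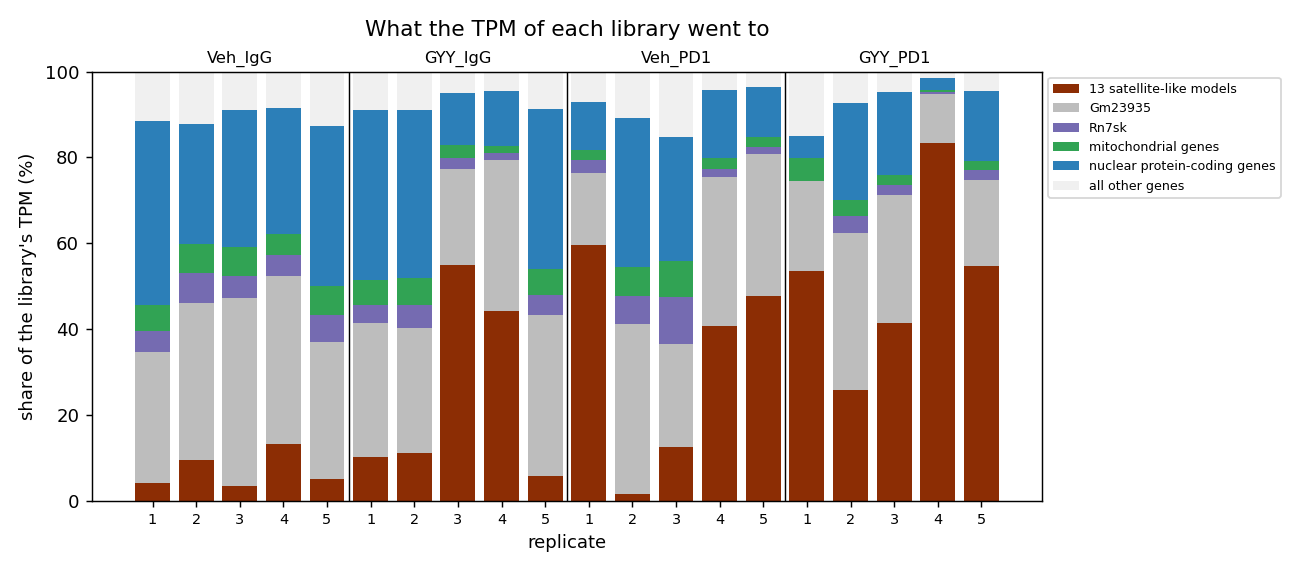
Share of each library's TPM in percent (vertical axis) for the 20 libraries, 5 replicates in each of 4 groups (horizontal axis), stacked by class of gene. The satellite-like share runs from 3.53% to 13.2% in Veh_IgG and from 25.8% to 83.4% in GYY_PD1.

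GYY4137 without the antibody was compared with vehicle to see what the donor does to the tumour. Genes induced by interferon gamma, a T cell and NK cell cytokine, lay higher in the donor-treated tumours. Relative to the library median, the mean of the 17 measured members was 0.38 ± 0.16 in GYY_IgG and -0.62 ± 0.52 in Veh_IgG on the log2 scale (SD, n = 5), and all 17 members had a higher mean. Every one of the 5 GYY_IgG libraries lay above all 5 Veh_IgG libraries (exact permutation p = 0.00794, adjusted over 34 lists p = 0.135). T cell markers showed the same order, with a list mean of -1.95 ± 0.42 in GYY_IgG and -2.88 ± 0.31 in Veh_IgG (SD, n = 5; exact permutation p = 0.00794, adjusted p = 0.135). Of the interferon gamma genes, Cxcl9, a chemokine that attracts activated T cells, had a log2 difference of 2.44 (SE 0.84). Ciita, the switch for MHC class II genes, had 1.30 (SE 0.51) and the interferon-induced GTPase Irgm1 had 0.81 (SE 0.32), with n = 5 per group. Cxcl9 lies on chromosome 5 (92321347 to 92328079).

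The interferon gamma list did not pass fry for the donor alone (median log2 difference 1.03, adjusted p = 0.887), nor did the T cell list (0.73, adjusted p = 0.887), and 0 of the 17 interferon gamma genes passed limma adjusted over the list alone. Camera called 12 lists with the preset correlation, with an adjusted p = 3.4e-22 for interferon gamma, and 0 with an estimated one, where the smallest adjusted p was 0.178. Among libraries under 20% satellite-like TPM, the interferon gamma mean on the coding-rescaled scale was 5.22 ± 0.05 in 3 GYY_IgG libraries and 4.22 ± 0.43 in 5 Veh_IgG libraries (SD; exact permutation p = 0.0179, the smallest that 56 splits allow). With every GYY_IgG library above every Veh_IgG library on this scale, any such subset gives this p. The lists closest to the chemistry of the donor showed no clear shift: targets of the antioxidant regulator NRF2 had a median log2 difference of -0.07 and genes of sulfide production and oxidation one of -0.11 (adjusted p = 0.887 for both). Single genes gave 0 calls with limma and 75 at an unadjusted p under 0.05, with 0 and 178 relative to the library median. On the deposited scale the median of all tested genes was lower by a log2 difference of -0.40. Without GYY_IgG replicate 2 or replicate 5 the count was 1, and with library weights it was 9.

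**Figure D2:**
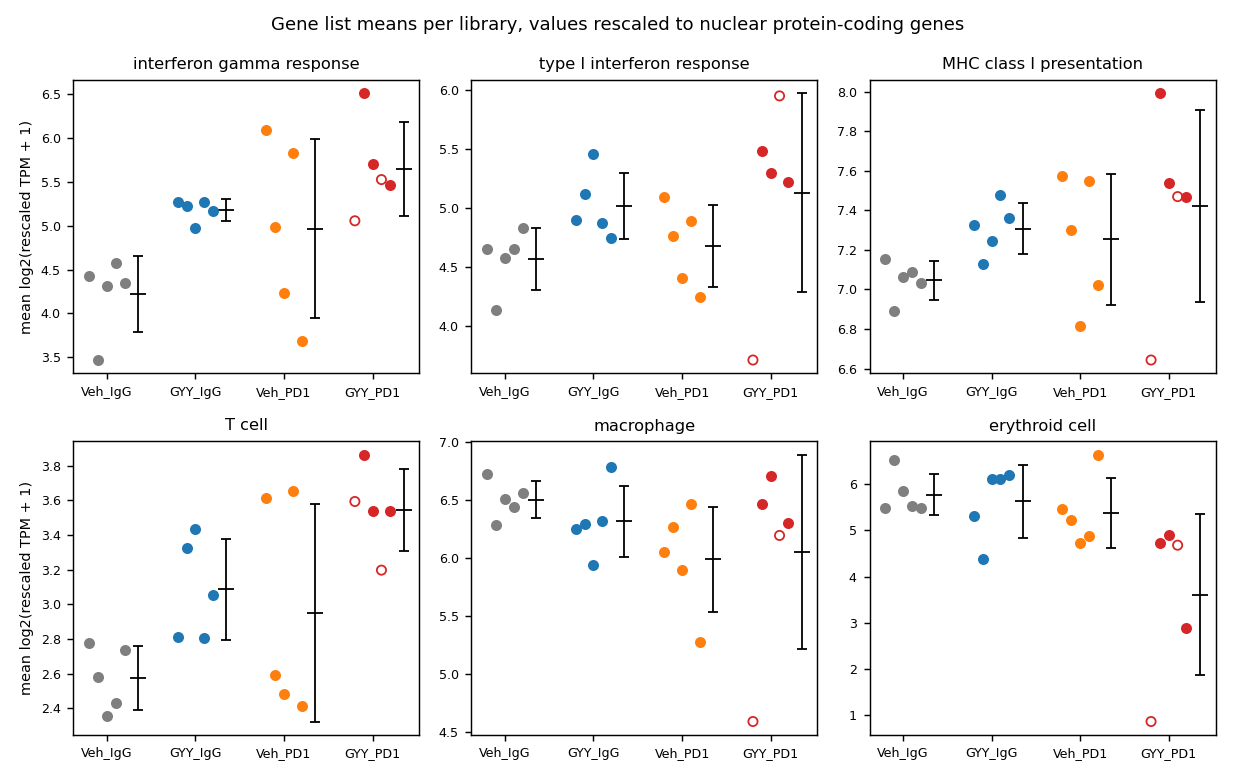
Mean log2(rescaled TPM + 1) over the measured members of 6 gene lists (vertical axes), on the scale of nuclear protein-coding genes, by group (horizontal axes). Each point is 1 library, open points are combination libraries 1 and 4, and bars give the mean and SD of the 5 libraries; the interferon gamma list runs from 3.47 to 4.57 in Veh_IgG and from 4.97 to 5.27 in GYY_IgG.

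Anti-PD1 alone was compared with the control antibody to see what checkpoint blockade does without the donor. The interferon gamma genes divided the treated tumours: on the coding-rescaled scale the list mean was 6.08 in Veh_PD1 replicate 1 and 5.82 in replicate 4, and from 3.69 to 4.99 in the other replicates, where Veh_IgG ran from 3.47 to 4.57. All 17 members had a higher mean in Veh_PD1 relative to the library median, among them Cxcl9 with a log2 difference of 1.85 (SE 0.84), the guanylate-binding proteins Gbp4 with 1.26 (SE 0.55) and Gbp2 with 1.00 (SE 0.45), and the transcription factor Irf1 with 0.56 (SE 0.24). The list as a whole did not pass (median 0.63, fry adjusted p = 0.938; difference of means 0.79, exact permutation p = 0.206). Between 2 Veh_PD1 and 5 Veh_IgG libraries under 20% satellite-like TPM the coding-rescaled means differed by 0.39 (exact permutation p = 0.476). Replicates 1 and 4 held 59.6% and 40.7% satellite-like TPM, and replicate 5, with the lowest list mean of the group (3.69), held 47.7%. No list was called by fry or by camera with an estimated correlation, and 10 were with the preset one. Single genes gave 0 calls with limma, with 223 at an unadjusted p under 0.05, and 0 and 273 relative to the library median. The median shift on the deposited scale was -0.90. With library weights, which give less weight to more variable libraries, limma called 12535 genes on the deposited scale, 148 higher and 12387 lower. Without Veh_IgG replicate 4 or Veh_PD1 replicate 3 the count was 1.

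The combination of both treatments was compared with neither. Relative to the library median, 5 gene lists rose and 2 fell. Interferon gamma response rose with a median log2 difference of 1.78 (adjusted p = 0.0125 with fry; adjusted p = 0.155 with an estimated correlation in camera, which does not pass). All 17 members were higher, 15 rose when adjusted over the list alone and 0 when adjusted over all genes. Over 22 alternatives the difference of the list ran from 0.84 to 1.99. Each of the 5 combination libraries had a higher list mean than every Veh_IgG library (exact permutation p = 0.00794, adjusted p = 0.045). Gbp2, which marks interferon-activated cells, was 4.69-fold higher (log2 2.23, SE 0.45), Ciita 5.19-fold (log2 2.38, SE 0.51) and Irgm1 2.56-fold (log2 1.36, SE 0.32), with n = 5 per group. Gbp2 lies on chromosome 3 (142620602 to 142638008), Ciita on chromosome 16 (10480059 to 10528418) and Irgm1 on chromosome 11 (48861968 to 48871683). Type I interferon response, the antiviral program, rose with a median of 0.84 (adjusted p = 0.0397; adjusted p = 0.172 with an estimated correlation). Of its 20 members, 19 were higher and 9 rose adjusted over the list alone, led by Oasl2 (2.96-fold; log2 1.57, SE 0.30), Irf7 (2.41-fold; log2 1.27, SE 0.26), Zbp1 (3.18-fold; log2 1.67, SE 0.41) and Ifi44 (3.39-fold; log2 1.76, SE 0.43).

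MHC class I, T cell and immune checkpoint genes were also higher in the combination relative to the library median. MHC class I presentation rose with a median log2 difference of 0.53 (adjusted p = 0.0351; adjusted p = 0.155 with an estimated correlation), with all 14 members higher and 6 rising adjusted over the list alone. With a pseudocount of 5 TPM the median turned to -0.067. The members with the smallest p were H2-T23 (1.95-fold; log2 0.96, SE 0.22), the peptide transporter Tap1 (1.68-fold; log2 0.75, SE 0.18), the immunoproteasome subunit Psmb10 (2.08-fold; log2 1.06, SE 0.35) and H2-Q7 (2.05-fold; log2 1.04, SE 0.35). The T cell list rose with a median of 1.81 (adjusted p = 0.0472; adjusted p = 0.183 with an estimated correlation and 0.0899 in the permutation test), with 5 of 6 measured members higher and 3 rising adjusted over the list alone. The fry call ended in 14 of 20 cases with 1 library left out. Over 21 alternatives the difference of the T cell list ran from 0.48 to 3.24. The 3 were Cd3e (5.17-fold; log2 2.37, SE 0.64) and Cd3g (10.8-fold; log2 3.43, SE 1.12), parts of the T cell receptor complex, and the adhesion receptor Cd2 (3.07-fold; log2 1.62, SE 0.48). The receptor chain Trac had a log2 difference of 2.01 (SE 1.62). Over 18 alternatives the log2 difference ran from 0.78 to 3.86 for Cd3e and from 0.95 to 5.05 for Cd3g. These T cell genes were rare, with a mean of 0.588 ± 0.204 TPM for Cd3e in Veh_IgG and 1.02 ± 0.702 in GYY_PD1 (SD, n = 5). Immune checkpoint genes rose with a median of 0.80 (adjusted p = 0.0125; adjusted p = 0.155 with an estimated correlation and 0.274 rescaled to coding genes), all 4 measured members higher and 3 rising adjusted over the list alone. These were Havcr2, which encodes TIM-3 (2.33-fold; log2 1.22, SE 0.38), Entpd1, which encodes CD39 (1.68-fold; log2 0.75, SE 0.27), and Cd274, which encodes PD-L1 (1.80-fold; log2 0.85, SE 0.31). Vsir had a log2 difference of 0.47 (SE 0.31). The other members of the list, Pdcd1, Pdcd1lg2, Ctla4, Lag3, Tigit, Tox, Btla and Ido1, stayed under the filter. The result for immune checkpoint genes therefore covers these 4 measured members only. MHC class II presentation had a median of 1.26 with all 9 members positive and did not pass fry (adjusted p = 0.101; 0.0348 without Veh_PD1 replicate 5), although its list mean was higher in every combination library (exact permutation p = 0.00794, adjusted p = 0.045). Besides Ciita, its leading members were H2-Eb1 (log2 1.56, SE 0.61), Cd74 (1.10, SE 0.46) and H2-Ab1 (1.26, SE 0.56).

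Respiratory chain and globin genes went down in the combination relative to the library median. Oxidative phosphorylation fell by 0.48 on the log2 scale (median, adjusted p = 0.0397; adjusted p = 0.372 with an estimated correlation), with all 17 members lower and 3 falling adjusted over the list alone: Cyc1 (log2 -0.46, SE 0.14), Ndufb5 (-0.48, SE 0.16) and Cox7a2 (-0.82, SE 0.27). Atp5o had a log2 difference of -0.67 (SE 0.26). GYY_PD1 replicate 1 lay far below the other replicates, with a list mean of 0.73 against 2.55 to 2.92, and without it the median was -0.29. The erythroid list fell by 3.35 (median, adjusted p = 0.0397; adjusted p = 0.372 with an estimated correlation), all 5 members lower and 4 falling adjusted over the list alone, which were the adult hemoglobin genes Hba-a2 (log2 -3.87, SE 1.12), Hba-a1 (-3.35, SE 1.29), Hbb-bt (-2.70, SE 0.87) and Hbb-bs (-3.70, SE 1.45). GYY_PD1 replicate 1 had a list mean of -6.35, where the other replicates ran from -2.15 to 0.02, and without it the median was -1.58. Every combination library lay below every Veh_IgG library for both lists (exact permutation p = 0.00794, adjusted p = 0.045). Macrophage markers had a median of -0.45 (adjusted p = 0.396), kidney proximal tubule markers 1.03 (0.426), adipocyte markers 2.25 (0.275), mitosis genes -0.60 (0.129), DNA replication genes -0.43 (0.157), mitochondrially encoded genes -0.54 (0.119, and 0.0491 without Veh_IgG replicate 1), NRF2 targets -0.46 (0.165) and sulfide genes -0.55 (0.157), with the adjusted p of fry in brackets. GYY_PD1 replicate 1 weighed on several of these: without it the median was -0.07 for macrophage markers, -0.04 for NRF2 targets, -0.21 for sulfide genes, -0.36 for mitosis and -0.16 for DNA replication. For adipocyte markers GYY_PD1 replicate 3 had a list mean of 3.96, where the other replicates ran from -2.60 to -0.23. The kidney proximal tubule mean ran from -5.20 to 0.74 within Veh_IgG. Without combination libraries 1 and 4 the macrophage median turned to 0.027 relative to the library median. On the coding-rescaled scale without them the sulfide median was -0.09, while the mean of the list was higher in the combination (5.12 against 4.98). None of the other tested lists passed either, with adjusted p from 0.150 to 0.988: B cell, monocyte, neutrophil, dendritic cell, fibroblast, endothelial cell, kidney distal nephron, NF-kB and inflammatory cytokines, hypoxia response, glycolysis, integrated stress response, unfolded protein response, p53 targets, MYC targets, mesenchymal transition, cholesterol synthesis, immediate early genes and ribosomal protein.

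The direction of the 5 rising lists holds relative to the library median and not on the deposited scale, where the median of all tested genes was lower by a log2 difference of -2.09 and the medians of these lists were -0.13 for interferon gamma, -0.10 for T cell, -1.07 for type I interferon, -1.11 for immune checkpoint and -1.38 for MHC class I. With an estimated correlation camera called 0 lists, and with the preset one 15. The permutation test of list means did not call type I interferon (adjusted p = 0.0675) or T cell (adjusted p = 0.0899), each with 4 of 5 combination libraries above every Veh_IgG library. Rescaling to coding genes over all libraries ended the call for immune checkpoint (median 0.59) and oxidative phosphorylation (-0.67), with an adjusted p = 0.274, and for type I interferon (0.65) and MHC class I (0.33), with an adjusted p = 0.302. Over all libraries the difference of oxidative phosphorylation did not shrink on this scale, where GYY_PD1 replicate 1 had a list mean of 4.80. The mean was 6.98 in GYY_PD1, 7.60 there without combination libraries 1 and 4, and 7.79 in Veh_IgG. Rescaling kept the call for interferon gamma, T cell and erythroid. Without combination libraries 1 and 4, on the coding-rescaled scale, 6 lists were called by fry, with interferon gamma at 1.64 (adjusted p = 0.0285) and T cell at 1.02 (adjusted p = 0.0324), and the erythroid list at -1.76 was not (adjusted p = 0.0558). With an estimated correlation in camera interferon gamma did not pass there. Interferon gamma and immune checkpoint passed fry whichever single library was left out (adjusted p up to 0.0483). The call ended for MHC class I without Veh_IgG replicate 2, 3 or 4 or GYY_PD1 replicate 2 (adjusted p up to 0.0777). It ended for oxidative phosphorylation in 8, erythroid in 9, type I interferon in 11 and T cell in 14 of the 20 cases (adjusted p up to 0.146). Each of these last 4 lists lost its call without Veh_IgG replicate 2, 3 or 4, GYY_IgG replicate 1, 2 or 4, or Veh_PD1 replicate 2. Without Veh_IgG replicate 5 the call also ended for oxidative phosphorylation, erythroid and T cell, without GYY_PD1 replicate 5 for erythroid, type I interferon and T cell, without GYY_PD1 replicate 2 or 3 for type I interferon and T cell, without GYY_PD1 replicate 4 for type I interferon, and without GYY_IgG replicate 3 or 5 or GYY_PD1 replicate 1 for T cell. Because no control library lies over 20% satellite-like TPM and no combination library under it, the comparison could not be made within either class.

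**Figure D3:**
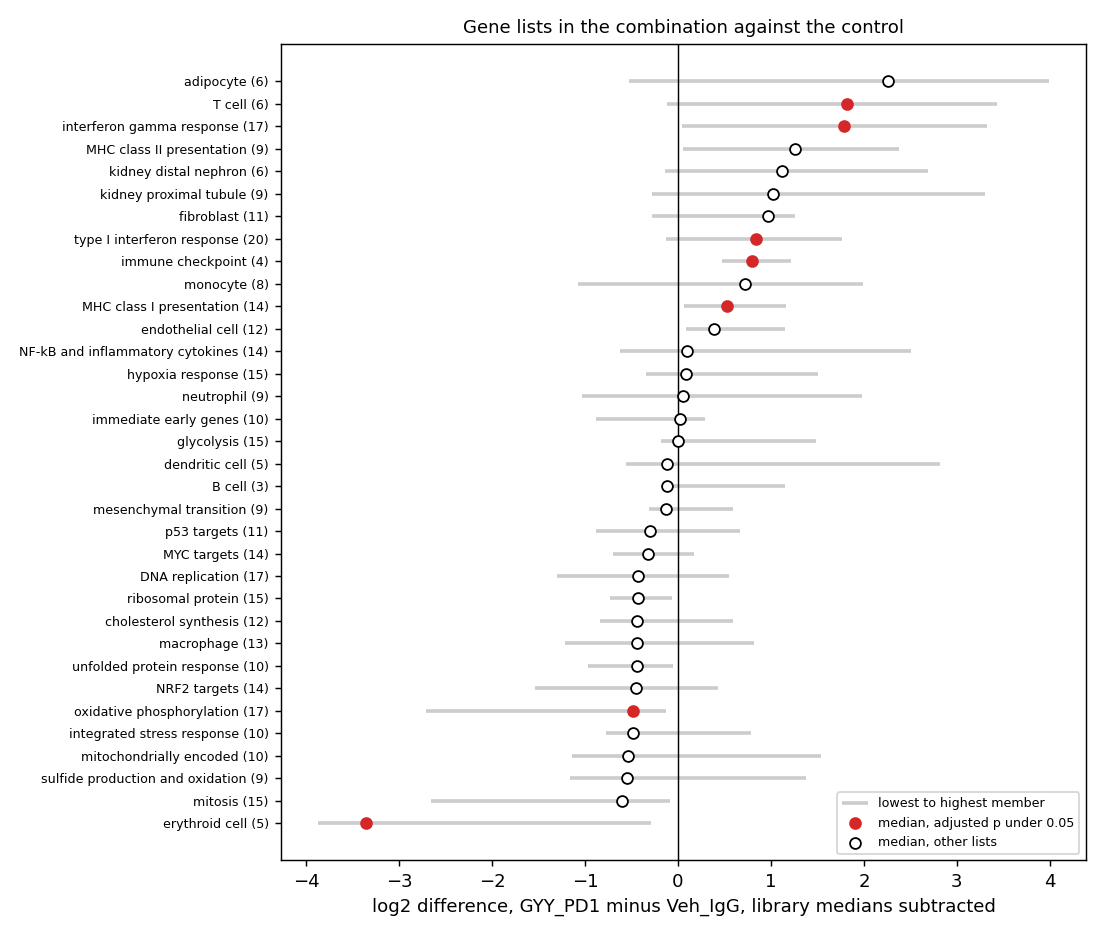
Median log2 difference between GYY_PD1 and Veh_IgG, library medians subtracted (horizontal axis), for the 34 tested gene lists with the number of measured members in brackets (vertical axis). Grey lines run from the lowest to the highest member and red points mark the 7 lists with an adjusted p under 0.05, from -3.35 for erythroid cell to 1.81 for T cell; on the deposited scale the medians of the 5 red lists on the right are below 0.

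Single genes in the combination were dominated by the shift of the whole profile. On the deposited scale limma called 10831 of 15422 genes, 48 higher and 10783 lower, and 19 of 34 lists, all lower. Relative to the library median it called 0 genes, with 2605 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0501. The 10 named falls were small RNAs, most of them listed at 0 TPM in the combination. Snord35a, a small nucleolar RNA on chromosome 7, averaged 24.2 ± 15.6 TPM in Veh_IgG and was listed at 0 in all 5 combination libraries, and the 5S ribosomal RNA copy n-R5s189 averaged 5.03 ± 2.51 TPM in Veh_IgG and was at 0 in all 5 (SD, n = 5). Snord34 and Snord110 were at 0 in 4 combination libraries and in no Veh_IgG library, and Mir7659, Mir7026, Mir7675, Mir5106, Mir301 and Mir511 were at 0 in 4 or 5 combination libraries and in 0 or 1 of Veh_IgG. The 10 RNAs were at 0 in 2 to 4 Veh_PD1 libraries and in 0 to 4 GYY_IgG libraries, so zeros were not particular to the combination. Their log2 differences depend on the floor written for 0 TPM. The named rises were Mir6244, listed at 0 in all 5 Veh_IgG libraries and in 1 of the combination, Mir9-3, the antisense RNAs Sardhos and Hnf1aos1, and Gng13, a G protein subunit, with a log2 difference of 3.73 on the deposited scale (adjusted p = 0.0236). Relative to the library median Gng13 had 5.65 (adjusted p = 0.214), and rescaled to coding genes without combination libraries 1 and 4 it had 1.82 (adjusted p = 0.522). The count on the deposited scale fell to 11 without Veh_IgG replicate 1, 13 without GYY_PD1 replicate 1, 12 without GYY_PD1 replicate 4 and 7 without combination libraries 1 and 4.

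The checkpoint genes, the tumour suppressor and the enzymes that make hydrogen sulfide were followed in every group. Pdcd1, which encodes PD1, stayed under the filter, with 0.129 ± 0.081 TPM in Veh_IgG, 0.368 ± 0.144 in GYY_IgG, 0.235 ± 0.210 in Veh_PD1 and 0.397 ± 0.475 in GYY_PD1 (SD, n = 5). On the coding-rescaled log2 scale Cd274 was at 4.56 ± 0.18 in Veh_IgG, 5.21 ± 0.55 in GYY_IgG, 5.21 ± 0.49 in Veh_PD1 and 5.20 ± 1.11 in GYY_PD1. Smarcb1 was detected in all groups, at 6.45 ± 0.23, 6.47 ± 0.33, 6.04 ± 0.29 and 5.97 ± 0.79 in the same order. Of the sulfide-producing enzymes, Cbs was at 1.84 ± 0.42, 2.96 ± 1.24, 2.17 ± 1.00 and 2.82 ± 1.21, Cth at 6.53 ± 0.31, 6.47 ± 0.23, 6.63 ± 0.08 and 5.81 ± 1.28, and Mpst at 6.02 ± 0.24, 5.62 ± 0.20, 5.84 ± 0.48 and 4.82 ± 1.42 (SD, n = 5). For the combination against Veh_IgG, relative to the library median, the log2 differences were -0.29 (SE 0.24) for Smarcb1, 1.38 (SE 0.80) for Cbs, -0.55 (SE 0.27) for Cth and -1.07 (SE 0.36) for Mpst, and none of the 5 tested genes passed when adjusted over all genes (limma adjusted p from 0.237 to 0.459). Much of these differences rests on combination libraries 1 and 4. Rescaled to coding genes without them, the values were 0.28 (SE 0.62) for Cbs, -0.09 (SE 0.15) for Cth and -0.34 (SE 0.21) for Mpst, and the sign of Smarcb1 turned, to 0.08 (SE 0.19).

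Adding GYY4137 to anti-PD1 was compared with anti-PD1 alone to see what the donor adds to the antibody. Genes encoded by the mitochondrial genome were lower and interferon genes higher, with neither passing fry. The mitochondrially encoded list had a median log2 difference of -0.73 (adjusted p = 0.103), and its mean was lower in all 5 GYY_PD1 libraries than in any Veh_PD1 library (means 7.24 ± 0.23 against 7.76 ± 0.27 relative to the library median; SD, n = 5; exact permutation p = 0.00794, adjusted p = 0.135). Of its members, the cytochrome oxidase subunits mt-Co2 and mt-Co3 had -0.79 (SE 0.22) and -1.33 (SE 0.52), mt-Nd4 -0.70 (SE 0.36) and mt-Cytb -0.80 (SE 0.57). Immune checkpoint genes had a median of 0.62 (adjusted p = 0.103), type I interferon genes 0.69 (adjusted p = 0.114) and interferon gamma genes 1.05 (adjusted p = 0.163), the last with 15 of 17 members higher. Camera called 15 lists with the preset correlation and 0 with an estimated one. limma called 12 genes on the deposited scale, all lower and with 1731 at an unadjusted p under 0.05. Those within the naming rule were Snord111, listed at 0 in all 5 GYY_PD1 libraries and at 10.2 ± 6.50 TPM in Veh_PD1 (SD, n = 5), and Mir8103, at 0 in 4 GYY_PD1 libraries. Relative to the library median 1 gene passed, the small nuclear RNA Gm22645, named after its values were seen (log2 -10.32, SE 1.53, adjusted p = 0.0376), with a difference that depends on the floor written for 0 TPM. The count was 1 without Veh_PD1 replicate 2 or 4 or GYY_PD1 replicate 4, 3 without Veh_PD1 replicate 3, and 33, 28 and 24 without GYY_PD1 replicates 2, 3 and 5. With library weights it was 395. Among libraries over 20% satellite-like TPM, the interferon gamma means of 5 GYY_PD1 and 3 Veh_PD1 libraries differed by 0.45 on the coding-rescaled scale (exact permutation p = 0.571).

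Adding anti-PD1 to GYY4137 was compared with the donor alone to see what the antibody adds. Cell division genes were lower in the combination: the mitosis list had a median log2 difference of -0.70 with all 15 members lower and 9 falling when adjusted over the list alone, although the list did not pass fry (adjusted p = 0.157). Ccnb1, the cyclin that starts mitosis, had -0.85 (SE 0.27), its kinase Cdk1 -0.73 (SE 0.27), Top2a -0.59 (SE 0.21) and Aurka -0.74 (SE 0.28). The erythroid list had a median of -3.14 (adjusted p = 0.157). Interferon gamma genes had a median of 0.83 (adjusted p = 0.361). Relative to the library median their mean was higher in all 5 GYY_PD1 libraries than in any GYY_IgG library (exact permutation p = 0.00794, adjusted p = 0.225). On the coding-rescaled scale GYY_PD1 replicate 1, at 5.05, lay within the GYY_IgG range of 4.97 to 5.27. Without combination replicate 1 the mitosis median was -0.43 and the erythroid median -1.36, and among libraries over 20% satellite-like TPM, without combination libraries 1 and 4, the mitosis median was -0.08. Camera called 16 lists with the preset correlation and 0 with an estimated one. limma called 10 genes on the deposited scale, all lower and with 9071 at an unadjusted p under 0.05, of which the rule names Mir8103. Relative to the library median it called 0, with 1507 at an unadjusted p under 0.05. The count was 10069, 9803 and 7780 without GYY_PD1 replicates 2, 3 and 5, 17 without Veh_PD1 replicate 1, 6 without GYY_IgG replicate 3 or GYY_PD1 replicate 4, 4 without GYY_IgG replicate 1 or 5, and 3 without GYY_IgG replicate 4. With library weights it was 11565. In the 5 GYY_PD1 and 2 GYY_IgG libraries over 20% satellite-like TPM the interferon gamma means differed by 0.53 (exact permutation p = 0.286).

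The average effect of GYY4137 over both antibodies set 10 mice against 10. It is the mean of the 2 donor effects given above and no separate evidence. Interferon genes were higher with the donor. Over 21 alternatives the difference of the interferon gamma list ran from 0.45 to 1.17. The type I interferon list had a median log2 difference of 0.60 with 16 of 20 members higher and 10 rising adjusted over the list alone, among them Irf7 (1.92-fold; log2 0.94, SE 0.19), Oasl2 (1.89-fold; log2 0.92, SE 0.21), Ifi44 (2.37-fold; log2 1.25, SE 0.30) and Zbp1 (2.04-fold; log2 1.03, SE 0.29). The interferon gamma list had a median of 1.04 with all 17 members higher and 14 rising adjusted over the list alone, among them Irgm1 (1.84-fold; log2 0.88, SE 0.22), Gbp2 (2.25-fold; log2 1.17, SE 0.32) and Gbp5 (2.61-fold; log2 1.39, SE 0.38). Both lists missed the threshold in fry (adjusted p = 0.0637) and passed the permutation test of list means (adjusted p = 0.0289). The same held for immune checkpoint at 0.44 (fry adjusted p = 0.0637, permutation adjusted p = 0.0371) and mitochondrially encoded genes at -0.47 (0.0637 and 0.0446), and, further from the fry threshold, for T cell at 0.74 (0.111 and 0.0446), MHC class I at 0.28 (0.128 and 0.0446) and oxidative phosphorylation at -0.29 (0.128 and 0.00408; -0.17 without GYY_PD1 replicate 1). Without Veh_PD1 replicate 1 or 4, fry called the interferon gamma, type I interferon, immune checkpoint, mitochondrially encoded and T cell lists. It also called type I interferon without GYY_PD1 replicate 1, immune checkpoint without GYY_PD1 replicate 5 and mitochondrially encoded genes without GYY_IgG replicate 3 (adjusted p from 0.0327 to 0.0484 in these cases). With an estimated correlation camera called 0 lists (smallest adjusted p = 0.166), and with the preset one 15. On the deposited scale, where the median of all genes was lower by a log2 difference of -0.78, the interferon gamma median was 0.32 and the type I interferon median -0.12. limma called 2 genes on the deposited scale, both lower and outside the naming rule, and 945 at an unadjusted p under 0.05. The 2 were the small nuclear RNA Gm22645 (log2 -7.24, SE 1.07, adjusted p = 0.0146) and the pseudogene Polr2k-ps (log2 -7.33, SE 1.23, adjusted p = 0.0455), named after their values were seen. The count ran from 0 without Veh_IgG replicate 2 or 3 or Veh_PD1 replicate 2 to 6 without GYY_PD1 replicate 5. It was 5 without GYY_PD1 replicate 3, 4 without GYY_IgG replicate 5, and 1 without Veh_IgG replicate 4 or 5, Veh_PD1 replicate 3 or 4, or GYY_PD1 replicate 1 or 4. With library weights it was 940.

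The average effect of anti-PD1 over both vehicles also set 10 mice against 10. Mitosis genes had a median log2 difference of -0.48 with all 15 members lower and 10 falling adjusted over the list alone, among them Ccnb2 (log2 -0.48, SE 0.15), Ccnb1 (-0.58, SE 0.19), Cdk1 (-0.54, SE 0.19) and Top2a (-0.42, SE 0.15). Without GYY_PD1 replicate 1, whose mitosis list mean lay far below the others, the median was -0.35. DNA replication genes had a median of -0.35 with 15 of 17 members lower, and interferon gamma genes one of 0.74 with all 17 higher and 5 rising adjusted over the list alone. Over 21 alternatives the differences ran from -0.58 to -0.15 for mitosis, -0.52 to -0.13 for DNA replication and 0.37 to 0.79 for interferon gamma. None of these lists passed fry (adjusted p = 0.173 for each) or the permutation test (adjusted p = 0.116 for each). Camera called 15 lists with the preset correlation and 0 with an estimated one. limma called 0 genes with 10074 at an unadjusted p under 0.05, and 0 with 1174 relative to the library median. The count was 0 or 1 without any 1 of 13 libraries and from 8011 to 10723 without GYY_IgG replicate 3 or 4, Veh_PD1 replicate 2 or 3, or GYY_PD1 replicate 2, 3 or 5. With library weights it was 13210.

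The interaction asks whether the effect of the donor differed with the antibody. No difference was detected in a named gene group: fry called 0 of 34 lists (smallest adjusted p = 0.820), camera 7 with the preset correlation and 0 with an estimated one. The donor effect on the interferon gamma list was 1.03 with the control antibody and 1.05 with anti-PD1. limma called 0 genes, with 153 at an unadjusted p under 0.05, and 0 with 376 relative to the library median. With library weights limma called 185 on the deposited scale, 151 higher and 34 lower. In the unweighted fit of all 20 libraries, neither limma nor fry showed a change that needs both treatments. Without GYY_PD1 replicate 3 or 5 the count was 3, and without GYY_IgG replicate 2 or 3, Veh_PD1 replicate 1 or 5 or GYY_PD1 replicate 2 it was 1.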

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

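The tests against other splits of the samples were chosen before the data were seen, and all other tests of this part were chosen after the results were seen. Of 116 groups of 5 libraries searched for a library far from the others, 6 had one, where about 5% are found by chance. In GYY_PD1 replicate 1, which came from 1 of the 2 mice numbered apart, the mitochondrial transcript mt-Nd6 stood at 18790 TPM, where the other replicates ran from 155 to 1059. The same library had a list mean relative to the library median of 0.73 for oxidative phosphorylation (others 2.55 to 2.92), -1.06 for mitosis (others 0.71 to 1.33) and 0.85 for NRF2 targets (others 2.35 to 2.50). Veh_IgG replicate 2 had an interferon gamma list mean of -1.54 (others -0.48 to -0.27), and Mpst stood at 35.5 TPM in Veh_IgG replicate 1 (others 17.5 to 20.8). The receptor genes, which no comparison of the study uses, averaged 0.0570 ± 0.0118 TPM in the combination and 0.0283 ± 0.0151 in Veh_IgG (SD, n = 5; exact permutation p = 0.0238).

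Most genes were lower in the combination on the deposited scale, with a difference in mean library medians of -1.91 log2. TPM sum to a constant, so a larger satellite-like share lowers all other genes. That share accounts for 57.5% of the difference over all 5 libraries, which leaves the remainder open, and for 89.1% over the 3 libraries other than replicates 1 and 4. Without those 2 libraries the difference was -0.76, so much of it rests on them. Only 1 of 100 splits, the real one, called as many genes (10831, highest other 7578), and the 2 treatments remain an untested biological explanation of the share itself.

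Interferon gamma genes were higher in the combination relative to the library median. The tests of background and of satellite content used the coding-rescaled values without combination libraries 1 and 4, where the median was 1.64 (adjusted p = 0.0285 with fry; adjusted p = 0.0817 with an estimated correlation, which does not pass). On the coding-rescaled scale the T cell mean minus the macrophage mean was higher in the combination by 1.42 (exact permutation p = 0.00794). Without combination libraries 1 and 4 it was higher by 1.08 (exact permutation p = 0.0179, the smallest that 56 splits allow). For these 2 lists this argues against a smaller tumour cell share that raises all other cell types alike, though the T cell genes were rare. Other cell type means were mostly higher too, such as fibroblast (4.81 against 4.48 in Veh_IgG), endothelial (4.33 against 4.06) and dendritic cell (3.85 against 3.18). Besides macrophage (6.05 against 6.50), only erythroid was lower (3.61 against 5.78). A smaller tumour cell share that raises most of the other cell types therefore stays open. Of 100 splits, 1, the real one, had an interferon gamma median as far from 0 (highest other 1.37). Every combination library already lay above every Veh_IgG library for this list, so this adds little to the permutation test of its mean. It also takes no account of the 34 lists tested. With the satellite-like share as a covariate the median was 1.47 on the same 18 libraries and the call ended (adjusted p = 0.122, over all alternatives from 2.2e-18 to 0.182) as the median SE of the members grew from 0.458 to 0.544, so this explanation cannot be told apart from the treatment in the combination, and background reads stay open too, since subtracting the receptor genes' mean (median 1.65) moved 0 of 11553 genes by more than 1 SE. With GYY4137 alone, the difference was 0.99 among libraries under 20% and 0.95 over all libraries, which argues against satellite content as its cause there. The exact permutation p = 0.0179 adds nothing, since every GYY_IgG library lay above every Veh_IgG library on this scale. A response to GYY4137 may contribute, as a hypothesis found and tested on the same data.

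The satellite-like share was higher in the combination. Genomic DNA may contribute to the share in the 10 libraries under 20%, none of which is a combination library. There the receptor genes' mean TPM rose with the share (Spearman's rho 0.830, permutation p = 0.0048, adjusted over 2 relations p = 0.0096; Pearson's r 0.911, permutation p = 0.00093, adjusted p = 0.00186; r 0.924 without the 2 farthest libraries). Among the 10 over 20%, which hold all 5 combination libraries, it could not be decided (rho 0.539, permutation p = 0.115; r 0.282, permutation p = 0.365; r 0.787 without the 2 farthest). The receptor mean was 0.0570 TPM in the combination and 0.0283 in Veh_IgG, where the share was 51.8% and 7.09%. The receptor genes thus did not rise in proportion to the share. The treatments stay open (exact permutation p = 0.00794), since satellite transcription and genomic DNA give the same reads in these values.

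For the 7 lists called in the combination relative to the library median, 1 of 100 splits, the real one, gave as many (highest other 2). The splits argue against chance for this count and do not test each list. These fry calls all end with an estimated correlation (smallest adjusted p = 0.155), and the permutation test of list means did not call type I interferon or T cell. For the 19 lists called on the deposited scale, 2 of 100 splits gave as many, and the other one called 20, so a count of that size also arose without the real groups. Chance stays open for the genes called with GYY4137 on anti-PD1 (11 of 100, real 12, highest other 11722), anti-PD1 on GYY4137 (7 of 100, real 10, highest other 12263) and the GYY4137 average (7 of 100, real 2, highest other 6). With a real count of 0, all 100 splits gave as many for GYY4137 alone (highest other 1), anti-PD1 alone (highest other 2), the anti-PD1 average (highest other 8573) and the interaction (highest other 8881). Splits that call several times the real count point to a structure of the samples, and what it is was not tested.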

How the results depend on the processing

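The alternatives chosen before the data were seen come first, and those chosen after are named as such. Over the alternatives other than single libraries left out, 1276 of 1453 values of named genes and 695 of 822 of lists kept direction and side of the threshold, with 7 and 12 reversed. With each library left out, 1552 of 1620 and 699 of 760 did. The cause of a change was not tested, except that fewer genes or samples were used where stated, and the unknown depth limits what can be said of genes near 0. Counts of genes past the threshold are given where they moved. With an adjusted p under 0.1, anti-PD1 on GYY4137 gave 10070 and the anti-PD1 average 11182. With a filter of 5 TPM, GYY4137 on anti-PD1 gave 6, anti-PD1 on GYY4137 5, the GYY4137 average 1 and the anti-PD1 average 7903, and the kidney proximal tubule list turned to -0.040 in the combination. With a pseudocount of 0.1, GYY4137 alone gave 1, anti-PD1 on GYY4137 4, the GYY4137 average 4 and the anti-PD1 average 8875. With a pseudocount of 5, GYY4137 on anti-PD1, anti-PD1 on GYY4137 and the GYY4137 average gave 0 and the anti-PD1 average 9548, and the MHC class I list turned to -0.067 and Tap1 to -0.021 in the combination. With library medians subtracted, the combination gave 0, GYY4137 on anti-PD1 1, anti-PD1 on GYY4137 0 and the GYY4137 average 0, and with quantile normalization all 4 gave 0. With only the groups compared (fewer samples), GYY4137 alone gave 1, the combination 13, GYY4137 on anti-PD1 3 and anti-PD1 on GYY4137 4. With the replicate number as a block, although the numbers were not taken to pair the mice, GYY4137 on anti-PD1 gave 5, the GYY4137 average 1 and the anti-PD1 average 8053. With library weights, GYY4137 alone gave 9, anti-PD1 alone 12535, GYY4137 on anti-PD1 395, anti-PD1 on GYY4137 11565, the GYY4137 average 940, the anti-PD1 average 13210 and the interaction 185. With robust shrinkage, GYY4137 on anti-PD1 gave 7, anti-PD1 on GYY4137 5 and the GYY4137 average 1. With the kidney covariate, the GYY4137 average gave 1 and the anti-PD1 average 9085, with 19 lists. With the mice numbered apart left out (fewer samples), GYY4137 alone gave 1, the combination 10, anti-PD1 on GYY4137 0 and the GYY4137 average 5. Of lists on the deposited scale, camera with the preset correlation called 7 for GYY4137 alone, 3 for anti-PD1 alone, 12 for the combination, 14 for GYY4137 on anti-PD1, 11 for anti-PD1 on GYY4137, 13 for the GYY4137 average, 10 for the anti-PD1 average and 5 for the interaction. With an estimated correlation it called 0 for the combination, library medians subtracted gave 7 there, and permutation of list means gave 20 for the anti-PD1 average. Of alternatives chosen after seeing the data, a pseudocount of 1 gave 1 for GYY4137 alone, 1 for GYY4137 on anti-PD1, 0 for anti-PD1 on GYY4137, 4 for the GYY4137 average and 9431 for the anti-PD1 average. Without combination libraries 1 and 4 (fewer samples), the combination gave 7, GYY4137 on anti-PD1 1, anti-PD1 on GYY4137 0 and the GYY4137 average 0, and in the combination the macrophage list turned to 0.027 and Smarcb1 to 0.041, the same values as with library medians also subtracted. The count was 0 for the combination, both comparisons of 1 treatment on the other and the GYY4137 average with medians subtracted and these 2 libraries left out, rescaled to coding genes with or without them, with the satellite covariate on either scale, and with the receptor background subtracted. Within the libraries over 20% satellite-like TPM it was 0 for both comparisons of 1 treatment on the other. Rescaled to coding genes without the 2 libraries, 6 lists were called for the combination and 1 for the GYY4137 average, and in the combination the macrophage list turned to 0.066 and Smarcb1 to 0.084. With the satellite covariate added they were 0.41 and 0.17, the mitosis list turned to 0.022, DNA replication to 0.039 and Cbs to -0.25. With the receptor background subtracted the macrophage list was 0.048 and Smarcb1 0.085, and with medians subtracted and the covariate the macrophage list was 0.071. Within libraries under 20%, NRF2 targets turned to 0.080 and sulfide genes to 0.018 with GYY4137 alone. With each library left out in turn, the counts ran from 0 to 1 for GYY4137 alone and for anti-PD1 alone, 11 to 11818 for the combination (11 without Veh_IgG replicate 1, 13 and 12 without GYY_PD1 replicates 1 and 4), 1 to 33 for GYY4137 on anti-PD1, 3 to 10069 for anti-PD1 on GYY4137, 0 to 6 for the GYY4137 average, 0 to 10723 for the anti-PD1 average and 0 to 3 for the interaction.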

Other observations

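All values of this part were chosen after the results were seen. Of the lists with too few measured members to test, the cytotoxic lymphocyte list had 1 tested member of 12, the regulatory T cell list 1 of 8, the NK cell list 0 of 8, and the plasma cell and skeletal muscle lists 2 of 8 each. Mean TPM in Veh_IgG, GYY_IgG, Veh_PD1 and GYY_PD1 were 2.19, 4.25, 1.47 and 2.88 for Ccl5, a chemokine of cytotoxic lymphocytes. Ifng, which encodes interferon gamma, was listed at 0 in 9 of the 20 libraries, all 5 of Veh_IgG among them, and was highest in GYY_PD1 replicate 2, at 0.912 TPM, where no other library exceeded 0.322 TPM. The immunoglobulin light chain gene Igkc stood at 315 TPM in GYY_PD1 replicate 3, against at most 8.67 in any other library. The muscle genes Acta1 and Ckm stood at 126 and 18.4 TPM in Veh_IgG replicate 1, against at most 0.539 and 0.634 in any other library. Foxp3, the regulator of regulatory T cells, stood at 10.6 TPM in GYY_PD1 replicate 1 and at most at 0.746 TPM elsewhere.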
